A study of Mus musculus with 2 samples.

How the data were processed

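RNA levels were measured on the Affymetrix Mouse Genome 430 2 array in rib chondrocytes of mice at 5 days of age. There were 2 samples, 1 wild type and 1 with the V156D knock-in of Matn1. Per the labels' protocols, the ribs were dissected, the cells were released with collagenase, total RNA was extracted with TRIzol and 6 µg of it was used to make biotin-labelled cRNA. Per the series' design text, the RNA came from cells of 5 littermates that were pooled before extraction, so each array is 1 pool and the spread between animals was not measured. Whether 5 animals were pooled for each genotype, and their sex, is not given in the sources used here.

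The deposited values are probe set intensities on a linear scale, 1 per probe set and array, for 45037 probe sets. MAS5, the Affymetrix signal algorithm, is named in the submitters' processing notes without a version or settings. The scaling target, the background correction and any detection calls are not given in the sources used here. The values themselves do not settle the method. The log2 of 100% of them had no more than 5 decimals, within 0.05 of the last decimal, and the SD of the log2 ratio between the arrays was lowest, at 0.17, in the tenth of probe sets with the weakest signals. Both would follow from a summary made on the log2 scale, and MAS5 signals usually scatter most at low signal. Whether the arrays were scaled together is therefore unknown, and a difference at low signal may have been compressed by the background step. Affymetrix control probe sets were not analysed here, so RNA integrity was not checked from the arrays.

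Probe sets were named from GEO's platform annotation, with symbols updated by Entrez identifier against a RefSeq gene table of GRCm38.p6, in which 34741 of the 34945 probe sets with 1 symbol were found and none changed its name. A further 932 probe sets had several symbols and 9160 were unnamed here, and neither kind entered the gene comparison. No genome build was tied to the probe sets, so no coordinates are given. The log2 of each deposited value was used without further normalization. Each of 18193 genes was represented by its probe set with the highest mean log2 signal over both arrays. A signal floor was set at the 50th percentile of the mean log2 signal of all probe sets, 5.77 or an intensity of 54.6, and 11329 genes lay at or above it.

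With 1 array per genotype there is no replicate error, and no test, standard error or p-value is given. The number of arrays limits the precision of every value. The comparison is therefore between 2 arrays, and a difference between them is not shown to be a difference between genotypes. Genes were counted when their signals differed at least 2-fold. As a description of probe noise, the ratios of probe sets of 1 gene were compared, with exact (Clopper-Pearson) 95% intervals for shares that cover counting error only. For each gene list, the median log2 ratio of mutant over wild type was ranked among medians of 10000 random lists of the same size, each member drawn from the 200 genes nearest in mean signal. A list was said to stand apart when its median lay outside the central 95% of these random medians. Co-regulated genes vary together between any pair of samples, so such a percentile describes these arrays only.

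Before the data were examined, 12 primary lists and 25 other lists were fixed, together with the floor, the fold threshold, the alternatives and the rule for named genes. Of 587 list entries, 528 matched a gene value by symbol, and the other 59 had no probe set tied to that gene alone. The named genes were the 4 matrilins, the 12 highest and 12 lowest ratios at or above the floor among genes with a non-clone symbol whose probe sets at or above the floor shared a sign, and, among members at or above the floor, the 2 highest and 2 lowest of each primary list and the highest and lowest of each other list. Other genes are named only as chosen after their values were seen.

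Alternatives were centring on the array median, quantile normalization, a loess correction of the ratio for signal (span 0.3), an offset of 32 added before log2, floors at the 40th and 60th percentile or none, the mean over a gene's probe sets, leaving out probe sets that may match several transcripts (names ending in _s_at, _x_at or _a_at), thresholds of 1.5-fold and 3-fold, unmatched random lists, list means, and only members at or above the floor. The scripts were tested on simulated data with normal noise of the SD of the log2 ratios at or above the floor (0.27). The noise was drawn independently for each gene. Of 200 genes given a 4-fold change among 11329, 200 were counted, with 0 unchanged genes counted. Of 100 lists of 20 genes shifted by 0.3 on the log2 scale, 99 stood apart, against 6 of 100 unshifted lists. The simulated lists were picked at random, whereas real lists hold co-regulated genes, so these rates need not hold for the arrays. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.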

Results

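Gene expression was compared between rib chondrocytes of wild-type mice and of mice carrying the V156D mutation of Matn1, which encodes matrilin-1, an oligomeric protein of the cartilage matrix. The cells were taken at 5 days of age and each genotype was represented by 1 array of RNA from pooled cells. The arrays had similar signal distributions, with a median intensity of 54.3 for wild type and 55.1 for the mutant, and an interquartile range of 21.9 to 186 and of 22.3 to 184. The summed intensity was 14520461 and 14091199. The log2 signals of the arrays correlated with r = 0.994 across probe sets, which are not independent replicates. No replicate error exists for any value below, and higher and lower refer to the mutant array relative to the wild-type array.

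The transcript of the mutated gene was present at nearly the same level in both arrays. Matn1 had an intensity of 4373 in wild type and 4340 in the mutant, a log2 ratio of -0.01, which was 0.04 after the loess correction. An expression array is not designed to tell the alleles apart, so this value says nothing of which allele was expressed. Matn3, which encodes a matrilin of growth cartilage, had an intensity of 10082 in wild type and 9076 in the mutant, a log2 ratio of -0.15. Matn4 had a log2 ratio of 0.08. Matn2 gave -0.17 with its brightest probe set and 0.23 with the other, so its direction was not settled. None of the 4 matrilins differed 1.5-fold, and the list median of -0.08 lay at percentile 30.3 of random lists.

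Few genes differed strongly between the arrays, and the larger differences were mostly higher in the mutant. Of 11329 genes at or above the signal floor, 74 were at least 2-fold higher and 29 at least 2-fold lower, together 0.909%. At 3-fold the numbers were 16 and 2, whereas at 1.5-fold they were 193 higher and 229 lower. The central 95% of all log2 ratios ran from -0.55 to 0.49 with an SD of 0.27 over genes. Where a gene had at least 2 probe sets at or above the floor, these gave the same sign for 2560 of 4878 genes, or 52.5% (exact 95% interval 51.1 to 53.9), against 37.3% if signs were independent. Among the 40 such genes that differed 2-fold, 38 had probe sets of 1 sign, or 95% (83.1 to 99.4). The log2 ratios of the 2 brightest probe sets of a gene correlated with r = 0.536 across genes, which are not independent, and their difference had an SD of 0.26. Small differences thus lay within the disagreement of probe sets, which measures probe error within these arrays and not error between samples.

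**Figure D1:**
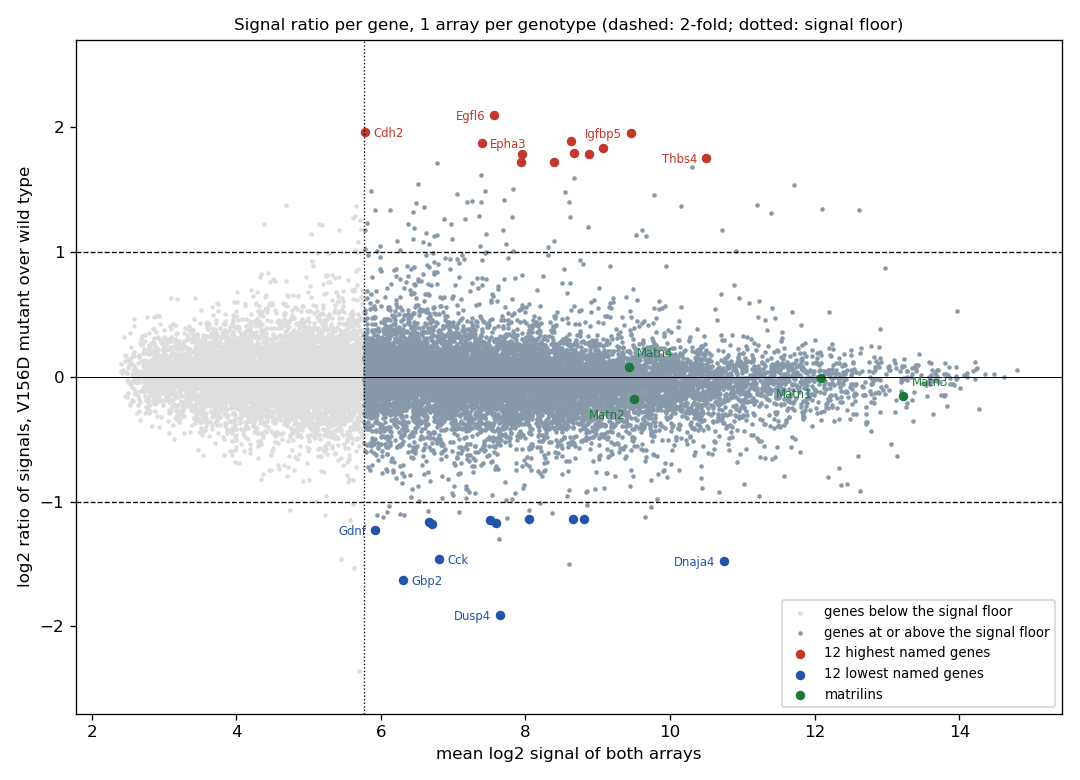
The log2 ratio of the mutant over the wild-type signal (vertical axis) is plotted for each gene against the mean log2 signal of both arrays (horizontal axis), with 1 array per genotype and no error bars. Dashed lines mark 2-fold differences and the dotted line the signal floor at 5.77. The 12 highest named genes are red, the 12 lowest blue and the 4 matrilins, which lie near 0, green, and some of these are labelled.

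The 12 named genes highest in the mutant array encode matrix proteins, adhesion molecules, a growth factor and its binding protein, among others. Markers of fibrous tissue and of vessels were higher in the same array, with list medians of 0.58 and 0.88. Egfl6, a secreted matrix protein, had the highest log2 ratio at 2.10, from an intensity of 91.2 in wild type to 391 in the mutant. Igf1, which encodes insulin-like growth factor 1, was 3.70-fold higher, and its 4 probe sets averaged a log2 ratio of 1.71 ± 0.32 (SD over probe sets, not over samples). Igfbp5, an IGF-binding protein, was 3.88-fold higher by its brightest probe set, but a second probe set gave a log2 ratio of 0.05. The cadherins Cdh2 and Cdh11 were 3.90-fold and 3.57-fold higher, Cdh2 from a wild-type intensity of 27.8, which lies below the floor, and 2.35-fold with the offset of 32. The ephrin receptor Epha3 was 3.67-fold higher. Matrix genes among the 12 were Kera, the keratocan of tendon and cornea, at 3.47-fold, Fndc1 at 3.45-fold (2.12-fold as the mean over its probe sets), Thbs4, a thrombospondin abundant in tendon, at 3.38-fold, Olfml2b at 3.31-fold and Cilp, a protein of the cartilage intermediate layer, at 3.29-fold. The integrin-like gene Itgbl1 was 3.44-fold higher. The intensity of Thbs4 was 782 in wild type and 2646 in the mutant.

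The 12 named genes lowest in the mutant array included a co-chaperone, a small heat shock protein and genes of immune signalling. They were picked by size, and the fixed interferon response list did not stand apart (median -0.05, percentile 17.0). Dusp4, a phosphatase acting on MAP kinases, had the lowest log2 ratio of the named genes at -1.91, from 386 in wild type to 103 in the mutant. Dnaja4, a co-chaperone of Hsp70, had intensities of 2857 and 1024, and its 3 probe sets averaged -1.53 ± 0.05 (SD over probe sets). Hspb8, a small heat shock protein, was 2.20-fold lower by its brightest probe set, while the mean over its 3 probe sets was -0.83 ± 0.58, short of 2-fold. The interferon-inducible GTPases Gbp2 and Gbp2b were 3.09-fold and 2.25-fold lower, Gbp2 to a mutant intensity of 45.2, which lies below the floor, and 2.32-fold lower by its second probe set. Both Gbp7 probe sets, named after their values were seen, had -0.25 and -0.17. Il15ra, which encodes a receptor chain for interleukin 15, was 2.20-fold lower, the cytokine gene Il23a 2.24-fold and the chemokine gene Cxcl3 2.20-fold. The peptide hormone gene Cck was 2.75-fold lower, the neurotrophic factor Gdnf 2.34-fold, Tmem140 2.27-fold and the transcription factor Glis3 2.22-fold. Gdnf, Tmem140, Il23a and Glis3 stayed lower but missed 2-fold when an offset of 32 was added before log2.

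Genes of the endoplasmic reticulum (ER) folding machinery were not higher in the mutant array as a group. Of 18 ER chaperones and folding factors measured, 11 had ratios below 0 and 7 above 0, and none differed 1.5-fold. The list median was -0.09, at percentile 15.9 of random lists, and it was -0.17, at percentile 0.51, when the probe sets of each gene were averaged. Hspa5, the main ER Hsp70 (BiP), had an intensity of 15812 in wild type and 13461 in the mutant, a log2 ratio of -0.23. Creld2 and Manf, genes known to respond to ER stress, had ratios of -0.40 and -0.32, and the BiP co-chaperone Dnajb11 had -0.38. Fkbp7 and Dnajc10 had the highest ratios of the list at 0.22 and 0.12. Hspa5 and Manf were named after their values were seen. All 12 heat shock genes were lower in this array, with a median of -0.68, so the preparations may have differed in stress. How far cell release changed the ER signals was not tested. The ER lists, here and in the next paragraph, thus do not show the stress state of the tissue.

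The other lists of the secretory pathway stayed close to 0. Among 17 protein disulphide isomerases and ER oxidation genes, 10 were above and 7 below 0, none differed 1.5-fold, and the median was 0.04 (percentile 96.0). Pdia5 and Tmx3 were highest at 0.19 and 0.12, Tmx3 at -0.02 without probe sets that may match several transcripts, and Ero1b and Pdia4 lowest at -0.32 and -0.21. Among 17 genes of ER-associated degradation, 12 were below 0, with a median of -0.09 (percentile 20.4), Syvn1, an ER ubiquitin ligase, lowest at -0.42, Ubxn4 at -0.29, and Edem2 and Sel1l highest at 0.28 and 0.09. The mean over all Sel1l probe sets was -0.08. The 10 sensors and transcription factors of the unfolded protein response divided evenly, with a median of 0.00 (percentile 72.7) and a mean of -0.10. Ern1, which encodes the sensor IRE1, was 1.51-fold lower, with 3 probe sets at -0.47 ± 0.14 (SD over probe sets). Eif2ak3, the sensor PERK, had -0.25, and Creb3l1 and Mbtps1 had 0.08 and 0.06. Among 23 translocon and COPII export genes the median was 0.01 (percentile 94.5) and the mean -0.06. The COPII coat gene Sec24a was 1.75-fold lower, Sec11c had -0.33, and Ssr1 and Sec11a had 0.17 and 0.12.

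Targets of the integrated stress response, the programme downstream of ATF4, were lower in the mutant array as a group, by small amounts. Of 22 members at or above the floor, 19 had ratios below 0 and 3 above, none differed 1.5-fold, and the median of -0.23 lay below all 10000 random lists. Mthfd2, a mitochondrial folate enzyme, was lowest at -0.49, and Trib3, a pseudokinase induced by ATF4, had -0.41. Wars and Ddit4 were highest at 0.18 and 0.08. The 3 probe sets of Wars averaged -0.06 ± 0.21 (SD over probe sets), so its sign depended on the probe set. The list stood apart in this direction under every alternative tried. Heat shock genes were lower in the same array, with a median of -0.68. Members such as Atf3 and Ddit3, named after their values were seen, were bright in both arrays. Atf3 had 10655 in wild type and 9034 in the mutant, and Ddit3 5050 and 4444. How much of these signals arose while the cells were released was not tested, so the list does not show the stress state of the tissue.

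Structural genes of cartilage had nearly equal signals in both arrays. Of 20 cartilage matrix genes, 14 were above and 6 below 0, and 1 differed 1.5-fold. Col2a1, which encodes the main cartilage collagen, had an intensity of 27997 in wild type and 29057 in the mutant, which was the highest value of each array. The proteoglycan gene Acan had a log2 ratio of 0.06 and Comp, a pentameric matrix protein, also 0.06. The list median of 0.05 lay at percentile 99.1, but at 95.2 after quantile normalization and at 87.9 against random lists not matched on signal. Cilp was the member that differed, 3.29-fold higher as given above, followed by Cilp2 at 0.54. Ucma and the collagen IX gene Col9a2 were lowest at -0.38 and -0.35.

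Regulators and stage markers of chondrocytes did not stand apart as measured by the brightest probe sets. The 13 transcription factors and signalling genes had a median of 0.08 (percentile 95.8), which was 0.02 over the 12 at or above the floor, 6 above and 6 below 0. When the probe sets of each gene were averaged it was 0.0927 and stood apart. Among those 12 the hedgehog pathway genes Gli1 and Ptch1 were highest at 0.43 and 0.21, and Sox9, the master regulator of chondrocytes, and Hdac4 were lowest at -0.29 and -0.26. The 2 probe sets of Sox9 averaged -0.39 ± 0.14 (SD over probe sets). The 12 hypertrophic and mineralising genes had a median of 0.03 (percentile 82.9) and a mean of -0.01. Mmp13, the collagenase of hypertrophic cartilage, was 1.70-fold lower, at 726 and 426, and the channel gene Panx3 had -0.37, or 0.01 as the mean over all its probe sets. Dlx5 and Mef2c were highest at 0.36 and 0.33.

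Cell cycle genes were higher in the mutant array as a group. Of 25 members at or above the floor, 20 had ratios above 0 and 5 below, none reached 1.5-fold, and the median of 0.27 lay above all 10000 random lists, and the list stood apart in this direction under every alternative, with a median of 0.13 when the probe sets of each gene were averaged. Fibrous tissue and endothelial markers were higher in the same array. Of these 25, the spindle factor Tpx2 and the mitotic kinase Aurkb were highest at 0.53 and 0.44. The replication helicase genes Mcm4 and Mcm2 were lowest at -0.53 and -0.15. The other Mcm genes of the list, named after their values were seen, had -0.07 (Mcm7), 0.03 (Mcm3), 0.05 (Mcm6) and 0.17 (Mcm5). The replication helicase genes were thus not higher as a set. The 15 apoptosis genes had a median of -0.08 (percentile 14.1) and a mean of -0.24, the latter at percentile 0.18 of random list means. The mean rested on 3 genes, Fas, Bid and Pmaip1, and the other 12 averaged -0.00. Pmaip1, named after its value was seen, had -1.54 with a mean signal below the floor. The death receptor gene Fas was 2.18-fold lower, at 1187 and 545, and Bid, a pro-apoptotic BCL2 family gene, 1.87-fold lower. Among members at or above the floor Casp9 and Bcl2 were highest at 0.35 and 0.22, Casp9 at -0.00 as the mean over all its probe sets.

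Markers of other cell types also differed between the arrays, and some of their list medians were farther from 0 than those of the lists above. Of 21 fibroblast, tendon and perichondrial genes at or above the floor, 19 were higher, 7 at least 2-fold, with a list median of 0.58 above all random lists. Of its 22 measured members, 20 were at or above the floor in the wild-type array as well, and 2 are also on the osteoblast list. Col14a1, a collagen of fibrous tissue, was 3.22-fold higher, from 705 to 2266, whereas Pdgfra had -0.10. Of 8 endothelial genes at or above the floor, 7 were higher and 3 at least 2-fold, and the median over all 12 measured was 0.88, above all random lists. Only 7 of these 12 were at or above the floor in the wild-type array. Cdh5, the cadherin of vessel walls, was 2.62-fold higher, from 55.1 to 144, and Egfl7 had -0.19, or 0.06 as the mean over all its probe sets. The osteoblast list, of which 4 genes are also on other lists, had a median of 0.40 over 8 genes, above all random lists. Of the 5 at or above the floor 4 had ratios above 0, and 1 differed 1.5-fold. That was Col1a1, the main collagen of bone and fibrous tissue and also on the fibroblast list, which was 2.54-fold higher, and Sparc had 0.00. The arrays also differed in sex-linked transcripts, and the sex of the animals is not given in the sources used here. Xist, expressed from the inactive X chromosome, was 1.55-fold lower and the Y-linked Eif2s3y 2.13-fold higher, or 0.76 on the log2 scale as the mean over its probe sets. Xist was at 7755 in wild type and 5006 in the mutant, and Eif2s3y at 230 and 490, all above the floor. Each pool thus appears to have held both sexes, with a larger male share in the mutant pool. That difference cannot be told apart from the genotype as a source of other differences.

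Heat shock genes were lower in the mutant array as a group. Their list was fixed as cytosolic, but its members Hspd1 and Hspe1, at -0.73 and -0.91, encode mitochondrial chaperonins. They are named after their values were seen. All 12 had ratios below 0 and 7 differed at least 1.5-fold, with a median of -0.68 below all random lists. The lowest was Hspb8 at -1.14 and the highest Hspa1b, an inducible Hsp70, at -0.15. Immediate early genes, which respond to tissue dissociation, had a median of -0.11 at percentile 6.30, with 15 of 17 below 0, Egr2 at -0.50 and Jund at 0.20.

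**Figure D2:**
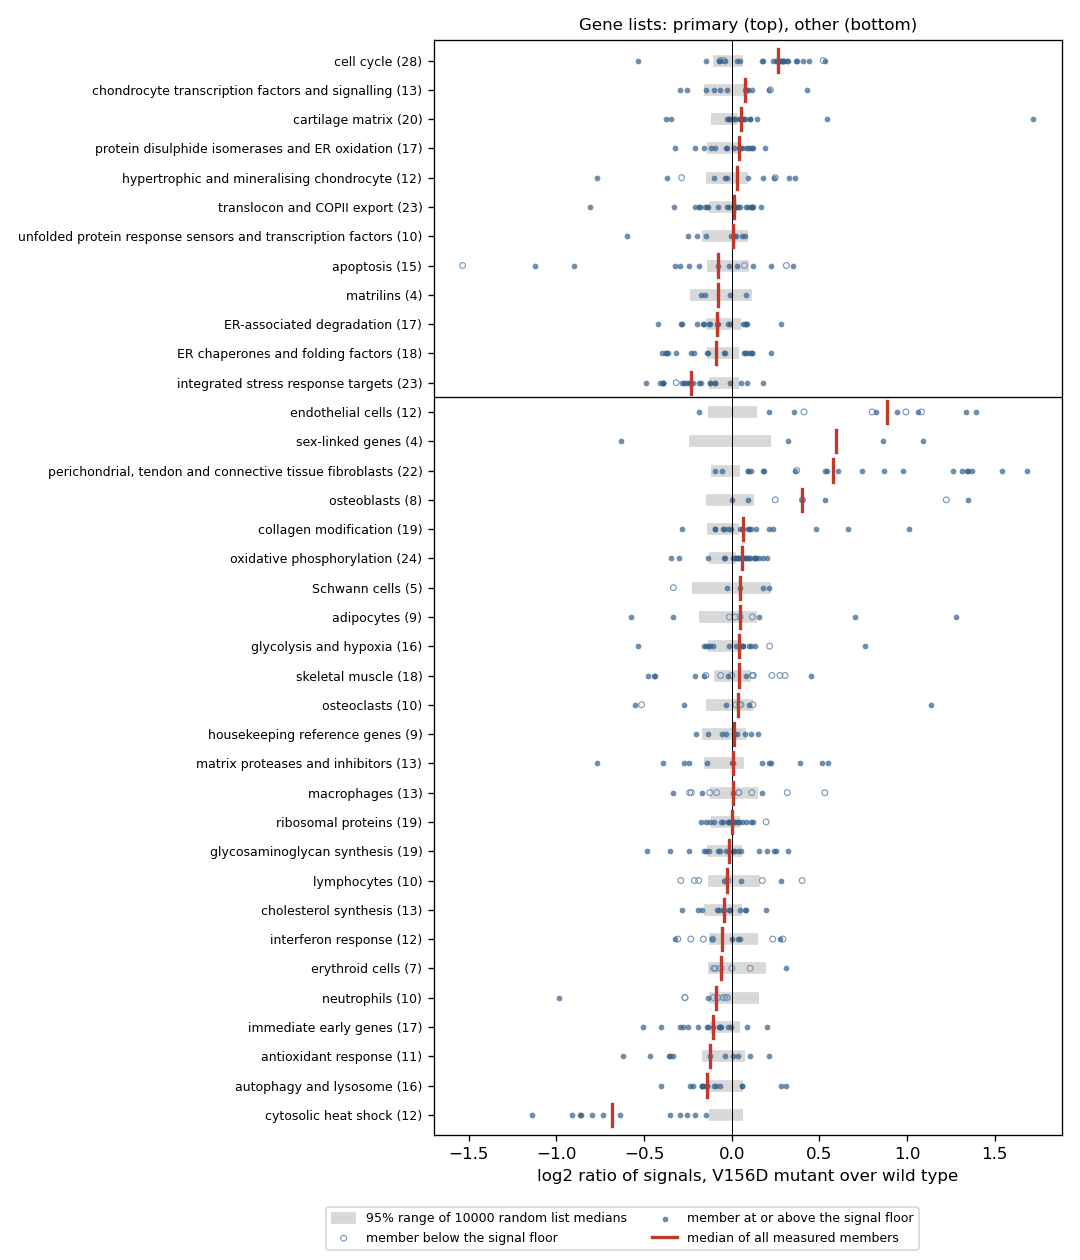
Each row is 1 gene list, with the number of measured genes in brackets, and the horizontal axis is the log2 ratio of the mutant over the wild-type signal. Dots are genes at or above the signal floor, open circles genes below it, red bars the list medians and grey bars the range of the central 95% of 10000 random list medians. The endothelial, fibroblast, osteoblast, sex-linked and cell cycle medians, and by a small margin those of cartilage matrix, collagen modification and oxidative phosphorylation, lie to the right of the grey bars, and the heat shock and integrated stress response medians to the left.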

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

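The tests in this part on single probe sets, heat shock genes and signal strength were set before their results were seen. The comparisons of fibroblast and of endothelial with other markers, and the use of cartilage matrix genes beside the fibroblast share, were chosen only after the list values were seen. Of 3074 probe sets at or above the floor that are not tied to 1 gene, and so lie outside the gene comparison, 12 were at least 2-fold higher in the mutant array and 5 at least 2-fold lower. The unnamed probe set 1441333_at was the highest of these, with intensities of 54.7 and 213. The lowest, 1457666_s_at, is listed for Ifi202b and for a predicted gene. It had 177 in wild type and 30.7 in the mutant, 5.75-fold lower, with the mutant value below the floor. A probe set listed for Ifi202b alone was 5.12-fold lower, at 118 and 23.0, with a mean just below the floor.

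Genes of fibrous connective tissue and of vessels were higher in the mutant array, with list medians of 0.58 and 0.88. A trend of the ratio with signal does not account for it, since the fibroblast median was 0.62 after the loess correction and still above all random lists. A lower share of chondrocytes would raise every other cell type alike, and it stays open. The pooled members of 8 other cell type lists at or above the floor had a median of -0.02. Fibroblast members exceeded this pool by 0.63 (bootstrap 95% interval over genes 0.20 to 1.30). At 2 times the floor signal they exceeded it by 0.60 (0.03 to 1.49). The comparison cannot decide the question, since most members of several pooled lists lay below the floor. Whether those cell types were present, and so could rise, was not tested. The intervals also treat co-regulated genes as independent. Endothelial members exceeded the same pool by 0.91 (0.23 to 1.31), but at 2 times the floor signal, where 4 were left, by 0.27 (-0.24 to 0.98). A larger share of perichondrial or other connective tissue cells in the mutant pool stays open. The 90.5% of fibroblast members at or above the floor with ratios above 0 only restates the pattern. Added cells would dilute cartilage matrix genes, whose median was 0.05, at percentile 99.1, with 14 members above 0 and 6 below. The members ran from -0.38 (Ucma) to 1.72 (Cilp). How large an added share these genes could show was not tested, so their median does not decide for or against added cells. An effect of the genotype on the fibrous tissue and vessel genes within chondrocytes also stays open. It was not tested because each genotype is 1 pool.

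Heat shock genes were lower in the mutant array in 12 of 12 members. A trend with signal does not account for it, since the median was -0.63 after the loess correction and below all random lists. A general response to dissociation that differed between the preparations may be involved. The immediate early genes, with a median of -0.11 at percentile 6.30, met neither bound set for that explanation in the reported setting. Their median ran from -0.14 to -0.04 over the settings. With 1 pool per genotype, no result for these genes could tell it apart from an effect of the genotype.

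A few single genes lay very far apart. One Rps9 probe set, 1434624_x_at, was 25.7-fold lower in the mutant array, at 2424 and 94.1, while the other Rps9 probe sets had log2 ratios of at most 0.12 in size, so the difference is likely one of that probe set and not of the gene. Ifi202b lies on another chromosome than Matn1 in the gene table, which argues against a strain segment around Matn1 as the source of its difference. A difference in strain background elsewhere in the genome was not tested.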

How the results depend on the processing

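No paired analysis was possible because each genotype has 1 array, and for the same reason no replicate could be left out. Depending on the threshold, 193 genes were higher and 229 lower at 1.5-fold and 16 and 2 at 3-fold. The offset of 32 left 45 higher and 13 lower, and 57 of its 58 genes were among the 103 found without it. The other alternatives kept both counts within 1.5 times. The mean over probe sets gave 77 genes, of which 68 were among the 103. The share of genes whose probe sets agree in sign was 50.3% with the floor at the 40th percentile, 55.7% at the 60th, 43.7% without a floor and 54.3% without probe sets that may match several transcripts. Averaging probe sets put the ER chaperone median at -0.17 and the median of chondrocyte regulators at 0.0927, both now apart from random lists. The apoptosis list stood apart by its mean, -0.24. The cartilage matrix list no longer stood apart after quantile normalization (median 0.0763) or against unmatched lists (median 0.0509, as reported). The cause of these shifts was not tested. All other primary lists stood apart, or did not, as reported under each alternative. Those that did were the integrated stress response (-0.25 to -0.17) and the cell cycle (0.13 to 0.28). The medians of 3 primary lists that did not stand apart changed sign under at least 1 alternative, those of the matrilins (-0.10 to 0.03), the translocon (-0.04 to 0.07) and the unfolded protein response sensors (-0.03 to 0.02). For 2 more, the disulphide isomerases and the hypertrophic genes, the mean had the other sign than the median. Of the 25 other lists 10 changed sign, and 0 of the lists that did had stood apart. The fibroblast, endothelial, osteoblast and heat shock lists stood apart in the same direction in all 10 settings run on them. Centring on the array median moved the median of all probe sets from 0.00 to -0.02. Of the 118 named genes, 32 differed 2-fold. Of these, 7 missed it under at least 1 alternative (Eif2s3y, Gdnf, Glis3, Hspb8, Il23a, Pcolce and Tmem140) and 0 changed sign. Of the others 12 changed sign, and the mean over the probe sets of Rps9 was -1.50, set by 1 probe set. The offset compresses low signals.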

Other observations

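Single genes outside the fixed lists, each chosen after its value was seen, included Cd34, Cd93, Notch3 and Rgs5, with log2 ratios of 1.47, 1.40, 1.10 and 1.48. The chemokine gene Ccl7 had -1.13, the epithelial cytokine gene Tslp -1.11, the NF-kB inhibitor gene Nfkbie -1.03 and the guanylate-binding protein gene Gbp3 -1.07. As single genes picked by size they say nothing of a group. Among the 50 array genes on each side of Matn1 in gene order, 0 of the 71 at or above the floor differed 1.5-fold (exact 95% upper bound 5.06%), against a median of 3.08% in 170 other windows. The fixed interferon response list had a median of -0.05 over 12 genes at percentile 17.0, with Bst2 at 0.28 and Irf7 at -0.32.

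Collagen modification genes had a median of 0.06 (percentile 99.2), in which Pcolce, an enhancer of procollagen cleavage, was 2.02-fold higher (log2 ratio 0.99 after centring and with the offset) and the collagen chaperone gene Serpinh1 had -0.29. Oxidative phosphorylation genes also had 0.06 (percentile 99.7), with none at 1.5-fold, Ndufa9 at 0.20 and Cycs at -0.35. Autophagy and lysosome genes had -0.14 (percentile 2.62), from Wipi1 at 0.31 to Atg5 at -0.40. That median was -0.02 (percentile 56.9) as the mean over probe sets, -0.07 (27.1) without probe sets that may match several transcripts, and -0.10 (2.42), standing apart, after the loess correction. Antioxidant genes had -0.13 (percentile 8.97), from Gsr at 0.21 to Gclc at -0.62. Glycolysis and hypoxia genes had 0.04 (percentile 94.0), from Car9 at 0.76 to Egln3 at -0.53. Matrix proteases and inhibitors had 0.01 (percentile 81.2), from Mmp14 at 0.55 to Mmp13 at -0.77. Glycosaminoglycan synthesis genes had -0.02 (percentile 67.4), from Chpf at 0.32 to Chsy3 at -0.49, and cholesterol synthesis genes -0.05 (percentile 47.3), from Lss at 0.19 (-0.01 as the mean over its probe sets) to Msmo1 at -0.29. Ribosomal protein genes had 0.00 (percentile 78.6) and housekeeping genes 0.01 (percentile 76.4), the latter from B2m at 0.15 to Ywhaz at -0.20. The 4 sex-linked genes measured had a median of 0.59 (percentile 99.95), with the Y-linked Kdm5d and Uty at 0.86 and 0.32.

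Of the remaining cell type lists none stood apart. Medians were 0.04 for skeletal muscle, 0.03 for osteoclasts, 0.05 for adipocytes, 0.05 for Schwann cells, 0.01 for macrophages, -0.02 for lymphocytes, -0.06 for erythroid cells and -0.09 for neutrophils, over all members measured. Over members at or above the floor they were -0.18 for muscle, with 6 of 8 below 0, -0.03 for osteoclasts, 0.15 for adipocytes, 0.11 for Schwann cells, -0.08 for macrophages, 0.05 for lymphocytes, 0.31 for erythroid cells and -0.56 for neutrophils, so the sign for muscle, osteoclasts, macrophages, lymphocytes and erythroid cells depended on the dim members. Members at or above the floor numbered 8 of 18 for muscle, 5 of 10 for osteoclasts, 5 of 9 for adipocytes, 4 of 5 for Schwann cells, 4 of 13 for macrophages, 3 of 10 for lymphocytes, 1 of 7 for erythroid cells and 2 of 10 for neutrophils. Of members at or above the floor, those that differed most were the protease gene Ctsk of the osteoclast list at 1.14, the lipase gene Lpl of the adipocyte list at 1.28 and the neutrophil marker Lcn2 at -0.99. In the same lists Acp5 had -0.55 and Pparg -0.57. The osteoclast list had 2 such members above and 3 below 0, and the adipocyte list 3 above and 2 below.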
